A study of Rattus norvegicus with 28 samples.

How the data were processed

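Total RNA of the amygdala of rat pups, from 50 to 80 mg of tissue per sample per the labels, was hybridised to Affymetrix expression arrays, 1 sample per array, 28 arrays in all. Each array was put in its group (condition and training) by its title, and replicate numbers were taken from the same title. The arrays were of 2 designs. Replicates 3 and 4 of the saline and of the 12-day groups were on the larger design, in paired and unpaired pups alike, and all other arrays were on the smaller one. The plan written from the labels had assumed that array design went with age, which the arrays did not bear out, so alternatives with the design as a block were added after the data were seen.

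The deposited values per array were log2 expression values of probe sets, and the submitters' processing notes name RMA and GCRMA without a version. Differences between group means of these values equalled the logarithm of the fold changes in the authors' rank product tables to within 0.000307, and those tables are named for GCRMA, so the values were taken as GCRMA-type summaries. Software, background model and probe annotation were not given in the sources used here. Array means lay between 6.00 and 6.05 in saline arrays, between 5.32 and 5.34 in corticosterone arrays and between 6.18 and 6.23 in 12-day arrays, so each condition was treated as normalized on its own, and levels were compared between agents relative to array medians. Values of single conditions, including ranges and plots, are given as deposited, and their levels were not taken to be on a common scale across conditions. The authors also deposited 1 comparison table per condition, whose header names are those written by the RankProd package, version not stated. Per the file headers, these tables hold the rank product statistic (a score), the fold change as a ratio of unpaired to paired pups, the estimated proportion of false positives (pfp, a score that can exceed 1), a p-value and a signed fold change. They were used for gene symbols and to compare the authors' calls with the rerun. All columns of per-sample values were used. The number of arrays limits the precision, and signal over background could not be judged, since no detection calls were used here.

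The 15866 probe sets present on both designs were tested, without control probe sets. Gene symbols came from the authors' tables and were updated through the RefSeq gene table of assembly GRCr8, which was used for names only, with no coordinates. Of the probe sets, 3079 were named through an accession, 1908 by a current symbol and 743 through an older symbol, 297 kept the symbol of the file, and 9839 had no symbol. This left 6027 probe sets with 1 symbol, for 4836 genes.

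Paired and unpaired pups were compared within each condition by rank products, the test named in the design text of the series. Differences between every paired and every unpaired array were ranked across probe sets, the null came from 100 shuffles within arrays with a fixed seed, and probe sets with a pfp under 0.05 were called, each direction apart. Standard errors came from limma 3.58.1 in R 4.3.3, in fits without the array sets described below, so they include the spread between sets. Limma also served as the other test (lmFit and eBayes with a mean-variance trend, Benjamini-Hochberg adjustment at 0.05). Limma was the main test for differences of the pairing effect between conditions and for corticosterone against saline, the latter with training as a covariate. Agreement of effects between conditions was Pearson's correlation across probe sets with a two-sided permutation p from relabelling training within conditions, exact unless more than 100000 relabellings exist. Rank products, permutations and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

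Before the data were examined, 23 gene lists of pathways and cell types were fixed, of which 22 were tested with camera (preset correlation 0.01, 1 probe set per gene, the one with the highest mean, adjustment over the lists of a comparison). Camera with an estimated correlation and fry were run beside it. Another 3 lists were added after called genes such as Th, Slc6a3 and Aldh1a1 had been seen, and were adjusted apart. The rule for named genes took, for each comparison of paired with unpaired pups, called probe sets with 1 symbol and a mean log2 of at least 5 in the higher group, 1 per gene, and among them the 12 with the smallest rank product per direction. It added every measured member of the dopamine list in every comparison, up to 4 called members of each other list, for limma the 10 genes with the smallest p per direction at the same level, and genes called in the same direction in corticosterone and 12-day but not in saline pups, of which there were 0. Results for some genes that this rule takes are not reported here.

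Arrays with the same replicate number were checked for pairing. In saline pups the deviations from the group means of same-numbered paired and unpaired arrays correlated at 0.537 to 0.860, and in 12-day pups at 0.598 to 0.734, all above the limit of 0.1. This pairing came largely from sets of arrays, replicates 1 to 2, 3 to 4 and, in saline pups, 5 to 7. Such sets held 67.6% of the variance between saline arrays and 68.2% of that between 12-day arrays, against 2.70% and 4.72% for training, and within sets the same-numbered arrays correlated at -0.141 to 0.489. No arrays were identical, and the lowest correlation between arrays of a condition was 0.974.

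The rank product, limma and camera were tried on simulated arrays with the real means and spreads and 200 changed probe sets. The noise of each probe set was drawn independently, so the joint variation of genes in real arrays was missing. The rank product recovered 99, 98 and 100 of 100 probe sets changed by 1 on the log2 scale in the saline, corticosterone and 12-day layouts, and limma 75, 83 and 61. Without any change limma called 0 probe sets in each layout, and the rank product called 0 when all probe sets had the same spread but 74, 31 and 20 with their real, unequal spreads, which its shuffled null does not take into account. Camera called 0 lists without change in each layout, against a median of 3 over other splits of the real saline arrays. These 0 calls of limma and camera therefore do not show how they behave on genes that vary together.

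The alternatives were limma in place of the rank product, the replicate number as a block, a mean of at least 5, quantile normalization, a pfp under 0.01, 1 probe set per gene, the mean over the probe sets of a gene, Spearman correlation, unpaired or paired pups alone and each array left out. Pairs within a design or set, sets alone, design or set as a block, array medians set to 0 and the exact tests of Th and Slc6a3 were chosen after the data were seen.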

Results

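Gene expression was measured in the amygdala of rat pups killed directly after a 45-min learning session. Each session held 11 presentations of a peppermint odor of 30 s, a tail shock of 1 s at 0.5 mA and an interval of 4 min between trials. Paired pups received the shock at the end of each odor, and unpaired control pups received it 2 min after the odor. The 28 arrays covered 3 conditions: 8-day pups given saline (7 paired and 7 unpaired), 8-day pups given corticosterone, the main glucocorticoid of the rat (3 and 3), and untreated 12-day pups (4 and 4). The title of the series names dopamine in the amygdala of infants as its topic, and the question addressed here was which transcripts differed between paired and unpaired pups in each condition. Values were log2 expression of 15866 probe sets, with array medians of 6.05 to 6.19 in the saline arrays, 5.06 to 5.09 in the corticosterone arrays and 6.38 to 6.46 in the 12-day arrays. The number of arrays limited the precision. The labels did not say whether a sample was 1 pup or a pool, so the limma and permutation p-values measure the spread between samples. The pfp does not measure it, as its null came from shuffles within arrays. Camera p-values with a preset correlation rest on a comparison between genes. Replicates 3 and 4 of the saline and 12-day groups were on another array design than the remaining arrays, in equal number for paired and unpaired pups.

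In 8-day saline pups, 4 genes of dopamine synthesis and transport had a probe set that was lower after paired training. Th, the rate-limiting enzyme of catecholamine synthesis, measured 5.55 ± 0.96 in paired and 7.28 ± 1.40 in unpaired pups (log2, mean ± SD, n = 7 each; probe set 1387075_at), a difference of -1.73 (SE 0.59) or 3.32-fold. Slc6a3, the plasma membrane dopamine transporter, measured 3.12 ± 1.03 against 4.92 ± 1.59, a difference of -1.80 (SE 0.65). Its size is not exact, as 5 of the 7 paired arrays (2.35 to 2.81) lay near the lowest levels of the arrays. Slc18a2, the vesicular monoamine transporter, was lower by a log2 difference of -1.18 (SE 0.36), and Ddc, the decarboxylase that forms dopamine, by -0.96 (SE 0.42). In the other direction Drd1, a dopamine receptor of striatal and amygdalar neurons, measured 8.32 ± 0.94 in paired and 7.24 ± 1.75 in unpaired pups, a difference of 1.09 (SE 0.68).

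Rank product analysis called 28 probe sets in the saline condition at an estimated proportion of false positives (pfp) under 0.05, 11 higher and 17 lower in paired pups. The authors' deposited table also lists 11 and 17, and all 11 and 17 were shared. Besides both probe sets of Drd1 (1.09 and 0.81), genes that were higher included Adora2a, an adenosine receptor of striatal projection neurons (0.67, SE 0.82). Besides the 4 dopamine genes, genes that were lower included Pmch, the precursor of melanin-concentrating hormone (-1.28, SE 0.95), Vamp1, a synaptic vesicle protein (-0.82, SE 0.38), the protease inhibitor A2m (-0.72, SE 0.53), Ugt8, an enzyme of myelin lipid synthesis (-0.70, SE 0.50), and Slc6a4, the serotonin transporter (-0.61, SE 0.44). Aldh1a1, a retinaldehyde dehydrogenase present in some dopamine neurons, was also lower (2.84 ± 1.22 against 3.86 ± 1.58) but lay below the level set for naming and was chosen after its values were seen. Another 13 called probe sets had no gene symbol, among them 1377434_at (0.87) and 1372208_at (1.00), which were higher, and 1389712_at (-1.40) and 1374684_at (-2.29), which were lower.

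Of the 15 measured genes of the dopamine list, Th, Slc6a3, Slc18a2, Ddc and Drd1 had a called probe set. A second probe set of Th measured 8.14 ± 0.20 in paired and 8.28 ± 0.45 in unpaired pups, and a second one of Slc18a2 5.67 ± 0.43 against 6.32 ± 0.31 (pfp 0.119), and neither was called. The second probe set of Slc6a3 was not called either, at 1.76 ± 0.03 against 1.99 ± 0.50 (-0.23, pfp 1.07), near the lowest levels in both groups. Drd2 differed by 0.52 (SE 0.56, pfp 0.208), Maob by -0.12 and Caly by -0.10, and Dbh, Gch1, Drd3, Drd4 and Drd5 lay near the lowest levels of the arrays, from 1.38 to 2.61 in mean log2, in both groups. When only same-numbered arrays were compared, the second Slc18a2 probe set and Drd2 (pfp 0.00308) became called, in a run that called 104 probe sets. An exact two-sided permutation test over all 3432 relabellings of the 14 arrays gave p = 0.0227 for Th and 0.0256 for Slc6a3, and relabelling within the replicate sets 1 to 2, 3 to 4 and 5 to 7 gave exact p = 0.00556 and 0.00833. These 2 genes were tested in this way after their values were seen. Within the 3 replicate sets the difference was -1.63, -1.09 and -2.23 for Th, -2.41, -0.60 and -2.19 for Slc6a3, 1.63, 0.64 and 1.02 for the first and 2.09, 0.74 and 0.01 for the second Drd1 probe set, and -0.68, -3.91 and 0.08 for Pmch.

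**Figure D1:**
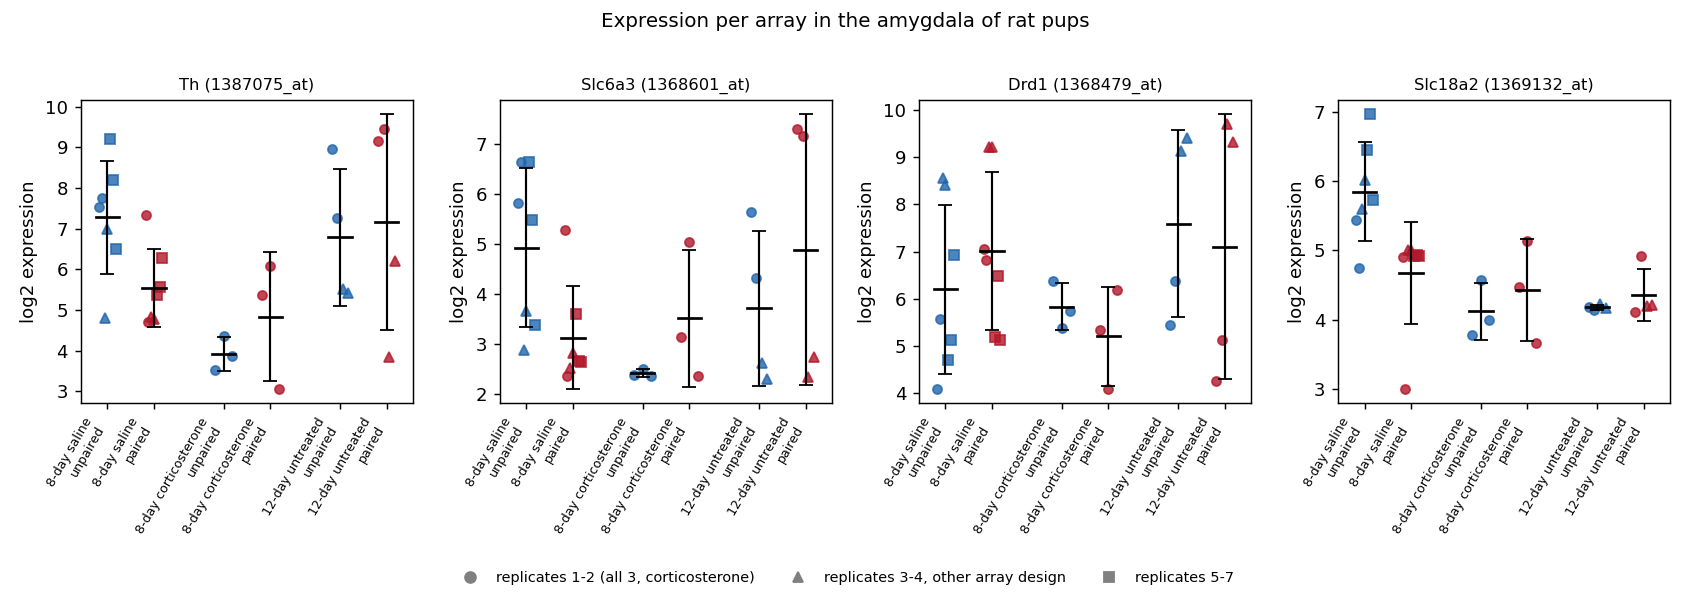
Log2 expression of Th, Slc6a3, Drd1 (its second called probe set) and Slc18a2 on each of the 28 arrays, by condition and training. Points are arrays, their shape gives the replicate set, horizontal lines are group means and bars are SD; in saline pups 6 of 7 paired arrays lay below the median of the 14 arrays for Th and 5 of 7 for Slc6a3, and the groups overlapped.

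Among the gene lists, camera with a preset correlation called the striatal projection neuron list higher and the oligodendrocyte and astrocyte lists lower in paired saline pups. The striatal list was higher in 12 of 13 genes (median 0.40, camera adjusted p = 5.27e-05, but adjusted p = 0.412 with an estimated correlation), with Penk, the precursor of enkephalins, at 11.31 ± 0.40 against 10.85 ± 0.64 and Rgs9, a regulator of striatal G-protein signalling, at 5.90 ± 0.28 against 5.52 ± 0.32. Oligodendrocyte and myelin genes were lower in 12 of 14 (median -0.14, adjusted p = 5.27e-05), such as Mag at 7.06 ± 0.63 against 7.44 ± 0.50 and Mbp at 10.88 ± 0.59 against 11.13 ± 0.75, both proteins of myelin. Astrocyte genes were lower in 9 of 14 (median -0.07, adjusted p = 0.0248). With an estimated correlation between genes none of these 3 calls held, with adjusted p = 0.415 for the myelin and 0.412 for the astrocyte list. The dopamine list had a median of 0.01, a mean of -0.13 and 8 genes higher and 7 lower (adjusted p = 0.344), tested with the probe set of highest mean per gene. The other 18 lists did not pass either, with adjusted p of 0.119 to 0.949, and adjusted over the list alone 0 genes of any list were called by limma. Of the 13 striatal genes 5 also belonged to another list, and the median difference was 0.63, 0.40 and 0.06 within replicates 1 to 2, 3 to 4 and 5 to 7.

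The precision of the saline count was low. Limma called 0 probe sets. At an unadjusted p under 0.05 it gave 72 of 15866, fewer than the 1 in 20 that chance gives. Its fit left the array sets, which held 67.6% of the variance, in the residual. With the set as a block it gave 1088 at an unadjusted p under 0.05, again with 0 calls. The rank product called 74 in simulated arrays with the real spread of each probe set and no change. It called 104 (49 higher, 55 lower) when only arrays of the same replicate number were compared. Th, Slc6a3 and Slc18a2 were called in each of the 14 runs that left out 1 array, against 10 runs for the first Drd1 probe set and 4 for Slc6a4, and the whole count was 16 without paired replicate 3 and 12 without paired replicate 4.

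In 8-day pups given corticosterone, 1 of the 2 probe sets of Th was called higher after paired training. It measured 4.83 ± 1.58 in paired and 3.91 ± 0.42 in unpaired pups (n = 3 each), a log2 difference of 0.92 (SE 0.75, pfp 0.01), on the probe set that was lower in saline pups. The other Th probe set measured 6.25 ± 0.09 against 6.11 ± 0.15 (0.13, SE 0.10, pfp 0.997) and was not called. The mean of the called probe set was below the level set for the leading genes, and Th is named as a member of the dopamine list. Slc6a3 measured 3.51 ± 1.37 against 2.41 ± 0.08, a difference of 1.10 (SE 0.63) that was not called (pfp 0.05). Its unpaired arrays, from 2.35 to 2.50, lay near the lowest levels of the arrays. Drd1 differed by -0.78 (SE 0.75), Drd2 by -0.37 (SE 0.39) and Maob, a monoamine oxidase, by -0.39 (SE 0.08), and these were not called by the rank product either.

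The rank product called 4 probe sets in this condition, all 4 higher in paired pups, and the authors' deposited table lists the same number, all shared. Th was the only one with a gene symbol. Ribosomal protein genes were higher in 42 of 51 by a small amount (median 0.04, camera adjusted p = 5.37e-08), as were immature neuron genes in 8 of 10 (median 0.09, adjusted p = 9.82e-04) and respiratory chain genes in 23 of 32 (median 0.02, adjusted p = 0.00155). All 3 had an adjusted p = 0.486 with an estimated correlation. Among immature neuron genes, Dpysl3, a cytoskeletal protein of growing axons, measured 11.28 ± 0.07 against 11.11 ± 0.05 and Stmn2, a tubulin-binding protein, 13.25 ± 0.05 against 13.16 ± 0.02. The other 19 lists did not pass (adjusted p of 0.0694 to 0.908), and the striatal list was higher in 3 and lower in 10 genes (median -0.17, adjusted p = 0.908). Adjusted over the list alone, limma called 1 gene of the dopamine list lower, Maob, and 0 over all genes tested.

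Limma called 0 probe sets in the corticosterone condition (449 at an unadjusted p under 0.05), and an exact permutation test gave p = 0.4 for Th and 0.3 for Slc6a3, where 3 against 3 arrays allow no p below 0.1. The rank product called 31 probe sets in simulated arrays without change, and leaving out 1 array gave from 1 call (without unpaired replicate 3) to 33 (without paired replicate 3), with Th called in 3 of 6 such runs.

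In untreated 12-day pups, the rank product called a small set of transcripts higher in paired pups. Whether a varying share of neighbouring tissue gave these calls was not tested. Ttr, the thyroid hormone carrier made by the choroid plexus, measured 13.56 ± 1.07 in paired and 11.46 ± 3.34 in unpaired pups (n = 4 each), a log2 difference of 2.10 (SE 1.48). Hcrt, the precursor of the hypothalamic orexins, measured 5.03 ± 1.61 against 4.16 ± 1.24, a difference of 0.87 (SE 0.86). Btg2, an activity-induced antiproliferative gene, measured 5.90 ± 1.55 against 5.04 ± 1.05, a difference of 0.87 (SE 0.79). Slc6a3 was higher as well, at 4.88 ± 2.71 against 3.71 ± 1.55 (1.17, SE 1.32).

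The rank product called 8 probe sets in 12-day pups, all 8 higher in paired pups, while the authors' deposited table lists 9, with 8 shared. Aldh1a1 (4.53 ± 2.64 against 3.71 ± 1.83) lay below the level for naming and was chosen after its values were seen, and 3 called probe sets had no gene symbol. Of the dopamine list Slc6a3 alone was called. The Th probe set called in the other conditions differed by 0.38 (SE 1.33, pfp 0.0583), the other Th probe set by 0.01 (SE 0.22), Drd1 by -0.46 (SE 1.07) and Drd2 by -0.41 (SE 0.86). The Slc18a2 probe set that was not called in saline pups differed by 0.85 (SE 0.51, pfp 0.0629). The one called in saline pups lay at 4.11 to 4.92 in paired and at 4.14 to 4.22 in unpaired arrays. Within replicates 1 to 2 and 3 to 4 the difference was 0.17 and 4.02 for Ttr, 1.13 and 0.62 for Hcrt, 0.42 and 1.31 for Btg2, and 2.26 and 0.08 for Slc6a3. The 4 Slc6a3 values of replicates 3 to 4 (2.30 to 2.73) lay near the lowest levels. Oligodendrocyte and myelin genes were lower in 13 of 14 (median -0.10, camera adjusted p = 0.0192), such as Mog at 9.30 ± 0.51 against 9.56 ± 0.05, a call that was lost with adjusted p = 0.68 with an estimated correlation. Without paired replicate 3 the median of this list was above 0 (0.019). The other 21 lists did not pass (adjusted p of 0.105 to 0.972). The thalamus and hypothalamus list was higher in 8 of 11 genes (median 0.23, adjusted p = 0.105), the immediate early list, which holds genes induced by neuronal activity, was higher in 10 and lower in 10 (median 0.03, adjusted p = 0.105) and the dopamine list in 8 and 7 (adjusted p = 0.283). Adjusted over the list alone, 0 genes were called.

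**Figure D2:**
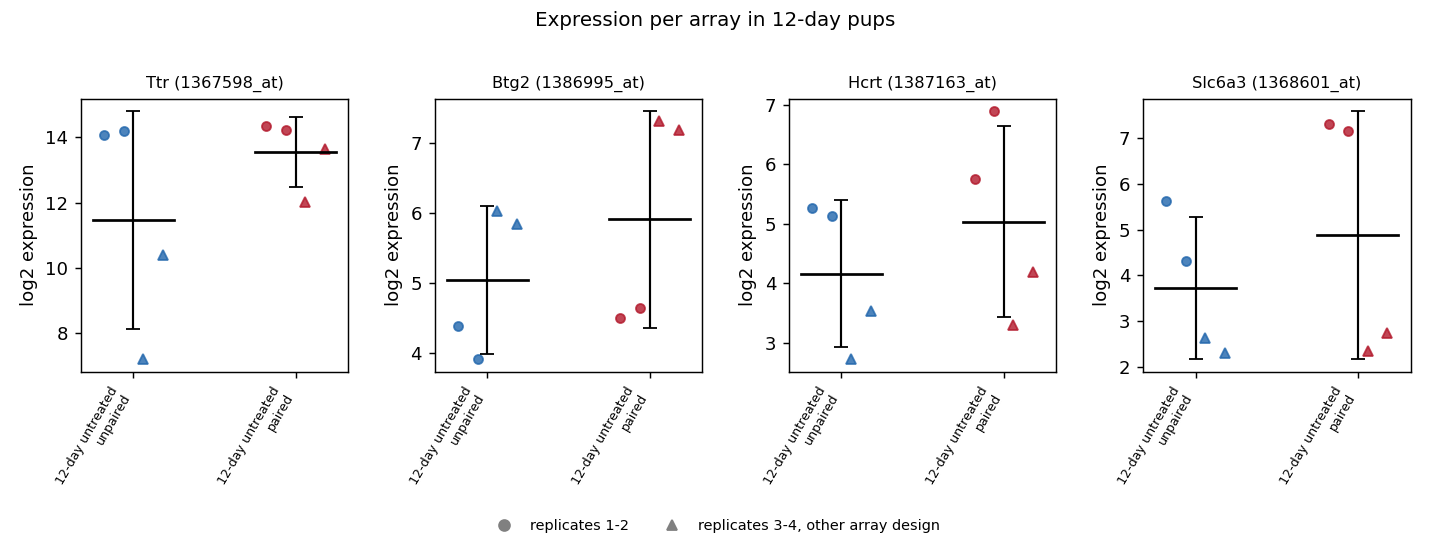
Log2 expression of Ttr, Btg2, Hcrt and Slc6a3 on each of the 8 arrays of 12-day pups, unpaired and paired. Points are arrays, their shape gives the replicate set, horizontal lines are group means and bars are SD; the replicate sets lay apart in both groups, and Ttr ranged from 7.21 to 14.36.

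Limma called 0 probe sets in 12-day pups. At an unadjusted p under 0.05 it gave 73 of 15866, again fewer than 1 in 20, with the array sets (68.2% of the variance) left in the residual. With the array design as a block it gave 468 and 0 calls. The rank product called 20 in simulated arrays without change. It called 34 (22 higher, 12 lower) when only arrays of the same replicate number were compared, where camera called 6 lists. Ttr kept its call in 3, Btg2 in 2, Hcrt in 3 and Slc6a3 in 4 of the 8 runs that left out 1 array, and the count ranged from 1 (without unpaired replicate 4) to 29 (without unpaired replicate 2).

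Whether the effect of pairing differed between conditions was tested directly. The difference for Slc6a3 was higher by 2.90 (SE 1.14) in corticosterone than in saline pups and by 2.97 (SE 1.39) in 12-day than in saline pups. These sizes are not exact, since each of the 3 conditions held Slc6a3 arrays near the lowest levels. Its second probe set gave 0.25 (SE 0.28) and 0.37 (SE 0.25). The difference was higher for the called Th probe set by 2.65 (SE 1.08) and 2.11 (SE 1.34), against 0.28 (SE 0.30) and 0.16 (SE 0.30) for the other Th probe set. Slc18a2 differed likewise, by 1.48 (SE 0.64) and 1.36 (SE 0.52), and Drd1 in the opposite direction, by -1.87 (SE 1.22) and -1.55 (SE 1.28). None of these passed the adjustment over 15866 probe sets, where every adjusted p rounded to 1. Limma called 0 probe sets in each of the 3 differences, with 65 (corticosterone minus saline), 53 (12-day minus saline) and 138 (12-day minus corticosterone) at an unadjusted p under 0.05. Each is fewer than 1 in 20 of the 15866 probe sets, from fits that left the array sets in the residual. With the array design as a block these counts were 1659, 255 and 375, again with 0 calls.

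By camera with a preset correlation the effect of pairing on the striatal list differed between conditions, a call that was lost with adjusted p = 0.532 (corticosterone) and 0.794 (12-day) with an estimated correlation. It was lower in corticosterone than in saline pups in 12 of 13 genes (median -0.59, camera adjusted p = 0.00839) and lower in 12-day than in saline pups in 12 of 13 (median -0.72, adjusted p = 0.00937). Between corticosterone and saline pups the oligodendrocyte list (0.10, adjusted p = 0.0148) and the ribosomal list (0.04, adjusted p = 0.00839) also differed. Leaving out 1 array turned both medians, to as low as -0.024 (without saline unpaired replicate 2 or corticosterone unpaired replicate 1) and -0.015 (without saline paired replicate 1 or unpaired replicate 6). Between 12-day and saline pups the immediate early list (0.05, adjusted p = 0.0344) and the thalamus and hypothalamus list (0.22, adjusted p = 0.0389) did, and between 12-day and corticosterone pups the ribosomal list (-0.03, adjusted p = 0.0292). The immediate early median turned without saline paired replicate 7 (-0.0033) and this ribosomal median without 12-day unpaired replicate 4 (0.0013). With an estimated correlation 0 lists were called in any of the 3 differences, the lowest adjusted p being 0.454, 0.499 and 0.4 with an estimated correlation. With the replicate number as a block, the striatal call between corticosterone and saline pups (adjusted p = 0.0658) and the immediate early call (adjusted p = 0.0779) were lost. With the array set as a block both were lost too (camera adjusted p = 0.0559 and 0.0957), as was the thalamus and hypothalamus call (0.0547). Adjusted over the list alone, 0 genes were called.

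No relation between conditions was detected in the effects of pairing across all probe sets. Pearson's r over 15866 probe sets, which are not independent replicates, was -0.0770 between saline and corticosterone pups (exact permutation p = 0.371), -0.0579 between saline and 12-day pups (permutation p = 0.770 from 100000 relabellings) and -0.00328 between corticosterone and 12-day pups (exact permutation p = 0.989), with an adjusted p of 0.989 for all 3. No probe set was called in the same direction in any pair of conditions. So few were called that independence gave an expected overlap of 0.0028, 0.0055 and 0.0020 higher probe sets in the 3 pairs. In the lower direction no overlap was possible, as only saline pups had such calls. The empty overlap therefore says nothing about shared effects. Th was called lower in saline and higher in corticosterone pups on the same probe set, and Slc6a3 and Aldh1a1 were called lower in saline and higher in 12-day pups. These calls do not establish a reversal, as the rank product also called unchanged probe sets in simulated arrays with unequal spreads. Exact permutation p was 0.4 for Th in corticosterone pups. For Slc6a3 in 12-day pups it was 0.486 over all relabellings and 0.111 within the replicate sets. The correlation between saline and corticosterone pups was -0.222 without paired corticosterone replicate 3.

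Corticosterone and saline arrays of 8-day pups differed at most probe sets, and from their array means the conditions appeared to have been normalized apart. The array medians differed by -1.04 and the deposited differences had a median of -0.72 over all probe sets, so levels are given here relative to each array's median. The SE beside them and the choice of genes by p came from limma on the deposited values. This does not remove a difference in spread: array SDs were 2.65 to 2.68 in corticosterone and 3.19 to 3.31 in saline pups. Across probe sets, which are not independent replicates, the deposited difference correlated with the saline mean at -0.728, so genes of low level tended to read as higher. All the higher genes with the smallest p lay below the array median in saline pups, from -3.71 (Adcyap1r1) to -1.43 (Star). Biglycan (Bgn), a matrix proteoglycan, was higher in corticosterone pups by 2.89 (SE 0.06; 0.35 ± 0.06, n = 6, against -2.54 ± 0.11, n = 14), Adcyap1r1, a receptor for the peptide PACAP, by 5.08 (SE 0.14) and the serotonin receptor Htr1b by 2.97 (SE 0.10). The phosphate transporter Slc20a2 was lower, with a difference of -3.01 (SE 0.09), as were Sik1, a salt-inducible kinase (-2.51, SE 0.09), and the growth factor Hbegf (-1.57, SE 0.06). The other genes with the smallest p were Pdk2, Gjd2, Hsd11b2, Star, Tns1, Nradd and Kcnj16, which were higher by 2.00 to 3.21, and Lenep, Apbb1, Txnl1, Vldlr, Picalm, Ppif and Pik3r2, which were lower, from -1.87 to -1.01. Of 13 measured genes of the glucocorticoid response list, limma on the deposited values called 4 higher and 7 lower adjusted over the list alone. Over all genes tested it called 11, where 12858 of all 15866 probe sets were called, so this share is not particular to the list. The 4 higher genes (Pdk4, Cdkn1a, Lcn2 and Cebpd) lay below a mean log2 of 5 with both agents. Among the 7 lower ones Klf9 alone turned relative to the median (-0.77 as deposited, 0.27 relative to the median). Relative to the median, Sgk1 differed by -0.48 (SE 0.10), Tsc22d3, which encodes a leucine zipper protein, by -1.03 (SE 0.18), the phosphatase Dusp1 by -1.46 (SE 0.16) and the metallothionein Mt1 by 0.68 (SE 0.20), while the deposited difference of Mt1 was -0.36 and was not called.

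Limma called 12858 probe sets between agents, 3349 higher and 9509 lower in corticosterone pups as deposited, and 11856, 7783 higher and 4073 lower, with array medians set to 0, so the share of each direction was set by the scaling. Camera called the synaptic plasticity (adjusted p = 0.0391), immature neuron (0.0391), ribosomal (0.0266) and respiratory chain (0.0357) lists lower than other genes, against 0.503, 0.424, 0.798 and 0.798 as adjusted p with an estimated correlation. It ran on the deposited values, whose difference correlated with the saline mean at -0.728, and took no account of level. Whether the level of these genes gave the list calls was not tested. The deposited median difference of the ribosomal list, -0.64, lay above that of all probe sets, so median and test differed in direction for this list. Per the design text of the series, paired and unpaired data were processed together within each condition. Agent and processing may therefore coincide, and their effects could not be told apart. Limma also called 5006 probe sets between saline arrays of replicates 1 to 2 and 5 to 7, which shared agent, age and array design.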

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

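The tests of the brainstem genes and of the saline arrays of replicates 1 to 2 against 5 to 7 were fixed before their results were seen, while the tests of differences within sets, with the set as a block, of the joint variation of striatal genes and of quantile normalization, and all tests on other splits of the arrays, were chosen after the results were seen.

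Single arrays stood apart from their group in 6 of the 92 groups of values that could be tested for it, where chance flags about 1 in 20 (4.6 of 92). For the called Slc18a2 probe set, paired saline replicate 2 was lowest at 2.996, with the nearest other array at 4.91, and at 12 days paired replicate 2 was highest at 4.92. Slc6a3 was highest in paired saline replicate 1, at 5.27 against 3.60 in the nearest other array. Gch1 was highest in paired saline replicate 7 (2.64) and in unpaired saline replicate 6 (2.53), and Drd5 in paired saline replicate 5 (2.58), all near the lowest levels of the arrays.

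The effect of pairing differed between conditions for several gene lists by the preset-correlation camera test of the difference. The median difference was -0.59 for striatal projection neuron genes, 0.10 for oligodendrocyte and 0.037 for ribosomal genes between corticosterone and saline pups. Between 12-day and saline pups it was -0.72 for striatal, 0.054 for immediate early, 0.22 for thalamus and hypothalamus and 0.26 for lateral hypothalamus genes. Between 12-day and corticosterone pups it was -0.035 for ribosomal and 0.26 for lateral hypothalamus genes. With an estimated correlation none of these calls held (adjusted p = 0.114 and 0.382 for lateral hypothalamus genes), and with the replicate number as a block the striatal call between corticosterone and saline pups (adjusted p = 0.0658) and the immediate early call (0.0779) were lost.

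Th and Slc6a3 were lower in paired than in unpaired saline pups. The array set is argued against as the whole cause by the layout: each set held both groups in equal number, so a shift of whole sets cancels. The mean of both genes was lower in paired pups within each of the 3 sets, by -2.02, -0.84 and -2.21. Th alone, which unlike Slc6a3 lay above the lowest levels, was lower by -1.63, -1.09 and -2.23. Both genes were chosen because they were called in these same arrays, so the differences within sets are not independent support. A varying share of neighbouring brain tissue could not be told apart from an effect of training: within groups and sets, the mean of Th and Slc6a3 correlated with that of 5 genes of brainstem neurons (Slc5a7, Slc17a6, Nefh, Nefm and Prph) at r = 0.239 over 28 arrays (permutation p = 0.319, rho = 0.335 with permutation p = 0.192, r = 0.257 without the 2 farthest arrays, adjusted p = 0.455 over 10 relations) and at r = -0.280 over the 14 saline arrays alone (permutation p = 0.395, rho = -0.156 with permutation p = 0.622, r = -0.198 without the 2 farthest arrays, adjusted p = 0.472), which decides neither way. The most abundant of these, Nefm (11.94 ± 0.42 in paired against 12.17 ± 0.32 in unpaired pups) and Slc17a6 (11.27 ± 0.46 against 11.67 ± 0.23), are also expressed by neurons of many other regions, and 1 of the 11 measured genes of the full brainstem list belonged to another list. That list and the list of midbrain dopamine neuron genes that do not handle dopamine were not called in saline pups (adjusted p = 0.161 and 0.608), and training remains an open explanation.

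The striatal projection neuron list was called higher in paired saline pups by camera with a preset correlation. The share of striatal tissue or cells in the samples may account for part of this, since within groups and sets 11 of these genes varied together over the 14 arrays, with a mean pairwise correlation of 0.343 (permutation p = 0.0001, the smallest that 10000 permutations can give). Shared regulation would give the same, 10 myelin genes varied together as well (0.371, permutation p = 0.0001), so this is not particular to striatal genes, and 5 of the 13 genes belonged to another list. A shift of whole array sets, alike in both groups, does not account for the difference. Each set held both groups in equal number, so such a shift cancels, and the median was above 0 in each set. With the set as a block, which leaves each difference as it is, the list stayed called (adjusted p = 0.00159). The highest adjusted p of its 20 alternatives were 0.412 with an estimated correlation and 0.995 with fry. This block moved the limma count at an unadjusted p under 0.05 from 72 to 1088. A difference present in some sets only could not be told apart from one in all, as the median went down to 0.063 within replicates 5 to 7, and an effect of training also remains open.

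Corticosterone and saline arrays differed at most probe sets. Location and spread of the deposited values are argued against as the whole cause, since limma still called 10399 probe sets after quantile normalization over the 20 arrays. A difference between sets of arrays is a candidate explanation: limma called 5006 probe sets between saline arrays of replicates 1 to 2 and of 5 to 7, which shared agent, age and array design. Per the design text of the series, paired and unpaired data were processed together within each condition. Array medians also parted by agent (5.06 to 5.09 against 6.05 to 6.19). Agent and processing may therefore coincide, and an effect of corticosterone could not be told apart from a difference in processing.

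Other splits of the same arrays gave counts at least as large as the real one in most comparisons. For the saline count of 28, chance could not be excluded, since 94 of 100 splits gave as many and the highest other split gave 1050. For the 12-day count of 8, chance could not be excluded either, with 26 of all 35 splits and a highest other of 1382. Such high counts point to a structure of the samples, as they came from splits that part the array sets unevenly. Over the splits that kept the sets balanced, 5 of 11 saline splits (others from 8 to 57) and 9 of 18 12-day splits (others from 0 to 21) gave as many. Among splits that part every same-numbered pair, 2 of 7 saline splits (others from 8 to 41) and 3 of 8 12-day splits (others from 0 to 21) did. The corticosterone count was 4 and the highest other 66 (9 of 10 splits gave as many), and the splits are too few for a share under 0.05. For the differences of effects the real counts were 0, so all 100 splits had to give as many, which decides nothing. Their highest others were 2342, 1467 and 2779, over splits that were not restricted to those that keep the sets balanced. For corticosterone against saline 1 of 100 splits, the real one, gave 12858 and the highest other 57. The array medians did not overlap between agents (5.06 to 5.09 against 6.05 to 6.19), and splits that mix the agents put this offset into the residual. The real split was therefore bound to give the most calls. These splits cannot tell an effect of corticosterone from a difference in normalization or processing.

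For the numbers of called lists chance could not be excluded in saline pups (3 lists, 75 of 100 splits, highest other 10), in 12-day pups (1 list, 35 of 35, highest other 8), in the differences of corticosterone minus saline (3 lists, 60 of 100, highest other 7), 12-day minus saline (3 lists, 72 of 100, highest other 8) and 12-day minus corticosterone (1 list, 94 of 100, highest other 8), and between agents (4 lists, 49 of 100, highest other 7). In corticosterone pups 3 lists were called and the highest other split called 8 (7 of 10 splits gave as many), and the splits are too few for a share under 0.05. These splits were not restricted to those that keep the array sets balanced. Over those that kept the sets balanced, 14 of 17 saline splits (others from 0 to 9) and 18 of 18 12-day splits (others from 2 to 7) gave as many lists, as did 13 of 19 for corticosterone minus saline (others from 0 to 7), 11 of 16 for 12-day minus saline (others from 1 to 6) and 48 of 54 for 12-day minus corticosterone (others from 0 to 8).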

How the results depend on the processing

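The tests by array design, by array set, within sets alone, without replicates 1 and 2 of both groups and with array medians at 0 were chosen after the data were seen; the other alternatives were planned.

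No count of called probe sets between paired and unpaired pups was stable, the cause was not tested, and the deposited values give no measure of signal over background beyond the level itself. In saline pups the rank product called 28 probe sets, 17 with a mean of at least 5, 13 at a pfp under 0.01 and 11 with 1 probe set per gene (fewer probe sets were tested in the first and last of these), 75 over pairs of the same set, 2, 10 and 15 within replicates 1 to 2, 3 to 4 and 5 to 7 alone (fewer arrays), and 14 without replicates 1 and 2 of both groups. Quantile normalization gave 28 and pairs of the same design 24. In corticosterone pups it called 4, against 0 with a mean of at least 5, 0 at a pfp under 0.01 and 0 with 1 probe set per gene, and 5 after quantile normalization. In 12-day pups it called 8, against 5 with a mean of at least 5, 0 at a pfp under 0.01, 40 over pairs of the same design and 16 within replicates 3 to 4. Limma called 0 in saline (72 at an unadjusted p under 0.05), 0 in corticosterone (449) and 0 in 12-day pups (73), and also 0 with the array design as a block in saline (809) and 12-day pups (468) and 0 with the set as a block in saline pups (1088). Between agents limma called 8172 with a mean of at least 5, 52 higher and 8120 lower, 10399 after quantile normalization, 4769 higher and 5630 lower, 11898 in unpaired and 11448 in paired pups alone. The Spearman correlation of effects between corticosterone and 12-day pups was 0.0355 where Pearson's was below 0.

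With the replicate number as a block the rank product called 104 probe sets in saline, 7 in corticosterone and 34 in 12-day pups, and limma with this block called 0 in each (2137, 320 and 428 at an unadjusted p under 0.05) and 0 in each of the 3 differences. On simulated arrays without change, pairs of the same set also gave more rank product calls than all pairs, 234 against 74 in the saline layout and 114 against 20 in the 12-day layout. In corticosterone pups the same-numbered arrays shared only a number, as their deviations correlated at -0.283, 0.0434 and -0.168, and 1 of the 3 paired arrays correlated best with its own number. Under the block, camera called 6 lists at 12 days and 4 between 12-day and corticosterone pups. The striatal list between corticosterone and saline pups (adjusted p = 0.0658) and the immediate early list between 12-day and saline pups (0.0779) were lost, and in saline pups a second Slc18a2 probe set (-0.65) and Drd2 (0.52, pfp 0.00308) became called. It ended or added no other call among the lists called without it and the named genes.

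The number of called lists fell to 0 with an estimated correlation in saline, corticosterone and 12-day pups, in all 3 differences and between agents, and to 0 with fry in each of these but agent, where fry called 21. With a mean of at least 5, 1 list was called in each of the differences from saline, 0 between 12-day and corticosterone pups and 2 between agents. With the set as a block 2 were called at 12 days, 1 between 12-day and saline and 3 between 12-day and corticosterone pups, where the striatal list between corticosterone and saline (adjusted p = 0.0559), the immediate early list (0.0957) and the thalamus and hypothalamus list (0.0547) were lost. With the mean over probe sets 4 were called at 12 days and 2 between agents. The striatal list in saline pups was called in 18 of 20 alternatives and higher in all 20, the myelin list in 17 and the astrocyte list in 12 of 20.

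Leaving out 1 array at a time gave 12 to 34 calls in saline pups (16 without paired replicate 3 and 12 without paired replicate 4), 1 to 33 in corticosterone pups (7 without paired replicate 1, 33 without paired replicate 3, and 7, 11 and 1 without unpaired replicates 1, 2 and 3) and 1 to 29 in 12-day pups (4, 2 and 23 without paired replicates 1, 2 and 3, and 26, 29, 2 and 1 without unpaired replicates 1, 2, 3 and 4). Of the 11 higher saline probe sets, 1 remained called without paired replicate 3, 1 without paired replicate 4, 1 without unpaired replicate 1, 4 without unpaired replicate 5 and 0 without replicates 1 and 2 of both groups. The differences gave 0 to 2 calls for corticosterone minus saline (2 without corticosterone paired replicate 2 and 2 without corticosterone unpaired replicate 3), 0 to 0 for 12-day minus saline and 0 to 3 for 12-day minus corticosterone (3 and 1 without the same arrays), and agents 12507 to 12956. The correlation of effects ranged from -0.222 to 0.0309 for saline with corticosterone, from -0.182 to 0.0891 for saline with 12-day and from -0.0777 to 0.0832 for corticosterone with 12-day pups. Its permutation p was under 0.05 only without corticosterone paired replicate 3 (-0.222, permutation p = 0.0107).

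The number of called lists ranged from 1 to 6 in saline pups (6, 5 and 1 without paired replicates 6 and 7 and unpaired replicate 2), from 3 to 6 in corticosterone pups (6 without paired and 5 without unpaired replicate 1) and from 0 to 4 in 12-day pups (4, 2, 0 and 2 without paired replicates 1, 2, 3 and 4, and 0, 4 and 4 without unpaired replicates 2, 3 and 4). It ranged from 0 to 6 for corticosterone minus saline (5 without saline paired replicate 1, 0 without corticosterone paired replicate 2, 1 and 6 without corticosterone unpaired replicates 1 and 3). For 12-day minus saline it ranged from 0 to 5 (1 and 5 without saline paired replicates 2 and 6, 5, 0 and 1 without saline unpaired replicates 1, 5 and 6, 0 without 12-day paired replicate 1, 5 and 0 without 12-day unpaired replicates 1 and 3). For 12-day minus corticosterone it ranged from 0 to 6 (4 and 0 without corticosterone paired replicates 1 and 2, 6 and 0 without 12-day paired replicates 1 and 4, 3 and 3 without 12-day unpaired replicates 1 and 3), and between agents it was 4 to 4.

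The direction of some values turned. Oligodendrocyte genes at 12 days ranged from -0.17 to 0.019 over the arrays left out (higher without paired replicate 3), and their difference between corticosterone and saline pups from -0.024 to 0.22 (turned without saline unpaired replicate 2 or corticosterone unpaired replicate 1). Ribosomal genes ranged from -0.015 to 0.077 between corticosterone and saline pups (turned without saline paired replicate 1 or unpaired replicate 6) and from -0.079 to 0.0013 between 12-day and corticosterone pups (turned without 12-day unpaired replicate 4), and immediate early genes between 12-day and saline pups from -0.0033 to 0.081 (turned without saline paired replicate 7). Aldh1a1 at 12 days ranged from -0.0050 to 1.78 (turned without paired replicate 2). In saline pups Pmch differed by 0.075 within replicates 5 to 7, 1377434_at by -1.29 and 1374684_at by 0.075 within replicates 3 to 4. For named genes and single lists 1765 values under an alternative kept direction and side of the threshold, 259 lost and 9 gained their call, 11 turned, and 50 that were called under neither setting changed sign. The planned use of another deposited set of values per array was not run, as no such set was used here.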

Other observations

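The tests of the 3 added lists, and the tests of Th and Slc6a3 against striatal, ribosomal, myelin and lateral hypothalamus genes, were chosen after called genes had been seen, while the choroid plexus and immediate early lists were planned.

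At 12 days camera with a preset correlation called the added list of lateral hypothalamus genes higher after paired training, while the planned thalamus and hypothalamus list did not pass (adjusted p = 0.105). Of 11 measured genes 10 were higher in paired pups (median 0.25, camera adjusted p = 2.94e-05 over the 3 added lists), a call that was lost with adjusted p = 0.130 with an estimated correlation. Cartpt, the precursor of a peptide of feeding and reward circuits, measured 8.67 ± 0.15 in paired and 7.73 ± 1.04 in unpaired pups (n = 4 each), a log2 difference of 0.94 (SE 0.45). Pmch differed by 0.85 (SE 1.08), Hcrt by 0.87 and Oxt, the precursor of oxytocin, by 0.89 (SE 0.94), and of these Hcrt alone was called by the rank product. The list differed from saline pups (median 0.26, 9 of 11 genes higher, adjusted p = 0.00237, against adjusted p = 0.114 with an estimated correlation) and from corticosterone pups (median 0.26, 11 of 11, adjusted p = 0.0130, against adjusted p = 0.382 with an estimated correlation). All 11 genes also belonged to another list. The name of the list is only a label, as it also held Oxt and Avp. The list was written after called genes had been seen and holds Hcrt, which was called higher in these same arrays, so its call is not independent support. The lists of midbrain dopamine neuron and brainstem genes were not called at 12 days (adjusted p = 0.469 and 0.636) or in corticosterone pups (0.924 and 0.870), and the lateral hypothalamus list was called neither in saline (0.619) nor in corticosterone pups (0.870).

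Among immediate early genes of 12-day pups, Nr4a1, an orphan nuclear receptor induced by activity, measured 9.60 ± 0.25 in paired and 9.17 ± 0.18 in unpaired pups, and Arc, a postsynaptic protein of activity-dependent plasticity, 8.82 ± 0.64 against 8.36 ± 0.65. Neither passed limma's test, and both were chosen after their values were seen. In saline pups Nr4a1 measured 6.60 ± 0.56 against 6.61 ± 0.36 and Arc 5.75 ± 0.28 against 5.61 ± 0.12.

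Some transcripts varied widely between arrays of a condition. Ttr ranged from 7.21 to 14.36 over the 8 arrays of 12-day pups, from 11.17 to 13.93 in saline and from 11.52 to 13.11 in corticosterone pups. Sostdc1 and Folr1, which like Ttr belong to the choroid plexus list, ranged from 2.04 to 8.17 and from 4.72 to 8.92 at 12 days. The choroid plexus and meninges list itself was not called at 12 days (median -0.01, mean 0.31, adjusted p = 0.859). Pmch ranged from 4.34 to 11.28 in saline and from 5.66 to 10.89 in 12-day pups, but from 9.14 to 10.03 in corticosterone pups. The unnamed probe set 1374684_at ranged from 2.39 to 12.17 in saline pups, from 2.34 to 10.68 in corticosterone pups and from 2.70 to 11.78 in 12-day pups.

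Over the 28 arrays, the mean of Th and Slc6a3 varied against that of 9 striatal genes within groups and sets (r = -0.634, permutation p = 0.0280, rho = -0.504 with permutation p = 0.0503), but the adjusted p over 10 relations was 0.280. Without the 2 farthest arrays r was -0.504, and over the 14 saline arrays alone it was -0.404 (permutation p = 0.424, rho = -0.262 with permutation p = 0.471, r = -0.313 without the 2 farthest arrays, adjusted p = 0.472). No other list tested this way passed either, and the lists were not compared with each other. Ribosomal protein genes gave r = -0.455 over the 28 arrays (permutation p = 0.163, rho = -0.394 with permutation p = 0.192, r = -0.383 without the 2 farthest arrays, adjusted p = 0.408) and -0.648 over the saline arrays (permutation p = 0.283, rho = -0.464 with permutation p = 0.323, r = -0.483 without the 2 farthest, adjusted p = 0.455). Myelin genes gave r = 0.433 over the 28 arrays (permutation p = 0.103, rho = 0.453 with permutation p = 0.0968, r = 0.474 without the 2 farthest, adjusted p = 0.343) and 0.259 over the saline arrays (permutation p = 0.671, rho = 0.226 with permutation p = 0.633, r = 0.181 without the 2 farthest, adjusted p = 0.671). Lateral hypothalamus genes gave r = -0.233 over the 28 arrays (permutation p = 0.0644, rho = -0.402 with permutation p = 0.0454, r = -0.130 without the 2 farthest, adjusted p = 0.322) and -0.217 over the saline arrays (permutation p = 0.288, rho = -0.314 with permutation p = 0.291, r = -0.051 without the 2 farthest, adjusted p = 0.455).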
